A study of Homo sapiens with 5 samples.

How the data were processed

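Poly(A)-selected RNA of H9 human embryonic stem cells was sequenced in 5 libraries, 1 for each combination of genotype and culture medium in the design. Wild-type cells were grown in basal, 5iLAF and 2iLAF medium, and cells with both copies of B3GALT5 knocked out were grown in basal and 2iLAF medium. Per the labels' protocols, libraries were made with a stranded TruSeq kit. The submitters' processing notes name Trimmomatic 0.39 (read trimming), Bowtie2 2.3.4.1 (alignment) and RSEM 1.2.28 (estimation of transcript and gene abundance), with genome build hg19. The annotation and the strand setting of RSEM are not given in the sources used here.

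The authors deposited 1 table of 26506 gene symbols with a TPM value and an FPKM value for each library, per the file headers. Deposited TPM values (transcript abundance scaled to the same total in each library) summed to 1000000 in 4 libraries and to 999999 in the B3GALT5-KO basal library. Deposited FPKM values (fragments scaled by gene length and library) stood in a near-fixed ratio to TPM among genes above 50 TPM in each library, between 0.484 and 0.531, so the units differ only by library scale. RSEM divides reads that fit several genes by an estimate. Values of near-identical genes, among them the metallothionein, alpha-globin, gamma-globin, defensin and histone genes, are therefore uncertain as single values. A gene and its antisense partner are separable only if strand was used, which is not stated. The table held no coordinates and none of the 15 mitochondrially encoded genes that were looked for, and 18 further columns were empty and not used.

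Read depth is unknown, because the table holds no counts. Low FPKM values were examined for steps of whole reads. Among the genes between 0.15 and 0.6 FPKM in both libraries of a pair, at most 4.84% shared a ratio within a bin of 0.05 on the log2 scale, so no step and no relative depth could be read. No counting interval or detection floor is given, and a gene at 0 is described as listed at 0.

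Each library was taken as its own group from the labels, and 6 comparisons of 2 libraries were made. Values were compared as log2((TPM + 1)/(TPM + 1)), a scale that understates ratios of low genes. Genes reaching 1 TPM in at least 1 of the 5 libraries entered (15761 genes). A gene was counted as higher or lower at a log2 ratio of at least 1 in size. With 1 library per group no test was possible, so counts and ratios describe these libraries and carry no p-value. Gene lists were summarised by their median log2 ratio, with a binomial order-statistic 95% interval of the median over members. Each median was also placed among the medians of 10000 random lists of the same size, matched in 20 bins of mean expression. A list is called above or below matched random lists where its median lay outside their middle 95%. That placement describes these libraries and is not a test across replicates.

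The comparisons, the size rule, 34 gene lists and the rule for named genes were chosen before the data were examined. The text names B3GALT5, the 10 highest and 10 lowest log2 ratios of each comparison among genes reaching 10 TPM in 1 of its libraries, up to 4 members of a list with the largest ratios or those at the highest level, and any member of the glycosphingolipid, core, naive and primed lists. Genes outside that rule are said to have been chosen after their values were seen. A further 8 lists of blood cell genes were written after the data had been seen. Pairs of libraries were compared by Pearson and Spearman correlation across genes, which are not independent replicates. Alternatives tried were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, median-ratio scaling, trimmed-mean scaling, and size rules of 1.5-fold and 4-fold. FPKM in place of TPM and leaving out the 65 tested blood cell genes were added later, as was taking blood cell lists whole, without the filter and with random lists matched on the WT 5iLAF level alone. Chromosome membership came from the RefSeq gene table of GRCh38, by symbol only, and no coordinates were used.

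Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedure was tested on simulated data made from the WT basal values of the 15761 genes. Noise was 0.15 on the log2 scale at every level, and 200 genes at or above 20 TPM were changed 4-fold. The procedure counted 100% of the raised and 100% of the lowered genes and 0 unchanged genes. Changes in low genes and their counting noise were not simulated, so counts among low genes are not checked. Of 200 unchanged lists of 20 genes drawn at random, 6% fell outside the middle 95% of random lists. Lists of genes that vary together were not simulated.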

Results

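Gene expression was measured by RNA sequencing in the human embryonic stem cell line H9. Wild-type (WT) cells were profiled in basal medium, which maintains the primed state of pluripotency, in 5iLAF and in 2iLAF. B3GALT5-knockout (B3GALT5-KO) cells were profiled in basal medium and in 2iLAF. 5iLAF and 2iLAF combine kinase inhibitors with LIF, activin A and FGF2 and are used to convert primed cells towards the naive state, a counterpart of the preimplantation epiblast. The labels record the WT 5iLAF and B3GALT5-KO 2iLAF libraries as naive, both basal libraries as primed, and the WT 2iLAF library as a control of intermediate, primed-naive state. Those states are taken from the labels alone, and 13 of 32 naive markers stayed below 1 TPM in all 5 libraries. The design asks how loss of B3GALT5 alters the transcriptome in each medium. Each of the 5 groups holds 1 library, so no difference has a replicate check and no error between cultures can be given. Depth is unknown. Between 13729 and 14156 genes were at or above 1 TPM per library, and the 10 most abundant genes took between 6.37% and 8.20% of TPM.

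B3GALT5 encodes the beta-1,3-galactosyltransferase that extends the globo-series glycosphingolipid Gb4 to SSEA-3. Its transcript stood at 9.31 TPM in WT basal, 5.98 in B3GALT5-KO basal, 5.13 in WT 2iLAF, 2.08 in WT 5iLAF and 1.17 in B3GALT5-KO 2iLAF. It was thus lower in each knockout library than in the WT library of the same medium, and present in both. The sources used here do not give the edited part of the gene, so transcript level does not check the knockout. Of the 7 globo-series enzymes, B3GALT5 included, 6 did not pass the size rule in WT 2iLAF, 3 in WT 5iLAF and 2 in B3GALT5-KO 2iLAF, each against basal medium, and the list medians lay inside the middle 95% of matched random lists. A4GALT, the Gb3 synthase, stood at 7.57 TPM in WT basal, 7.32 in B3GALT5-KO basal, 18.8 in WT 2iLAF, 22.7 in WT 5iLAF and 18.7 in B3GALT5-KO 2iLAF. FUT1, which fucosylates the globo-series end product, stood at 5.97 and 8.93 TPM in the basal libraries and at 4.18, 1.26 and 1.22 TPM in WT 2iLAF, WT 5iLAF and B3GALT5-KO 2iLAF. B3GALNT1, the Gb4 synthase, was at 2.19 TPM in B3GALT5-KO basal against 6.89 in WT basal. It was the 1 globo-series member of 7 to pass the size rule between the basal libraries, where the list median was -0.32, inside the middle 95% of matched random lists. Lacto-series and ganglio-series enzymes had medians of 0.03 and -0.03 in the same comparison, with no member of 12 and 9 passing the size rule. The 17 ceramide and early sphingolipid enzymes had a median of 0.24 (interval -0.08 to 0.31), above matched random lists, although no member passed the size rule and 6 had negative ratios. Among members were UGCG, the glucosylceramide synthase, at 25.6 against 19.9 TPM and B4GALT5, a lactosylceramide synthase, at 89.1 against 68.9 TPM.

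The libraries fell into pairs that did not follow genotype. Across 15761 genes, WT basal and B3GALT5-KO basal were most alike (Pearson correlation of log2(TPM + 1) 0.987, Spearman 0.986). WT 5iLAF and B3GALT5-KO 2iLAF came next, at 0.970 and 0.969. WT 2iLAF correlated with WT basal at 0.946, with WT 5iLAF at 0.891 and with B3GALT5-KO 2iLAF at 0.856 (Pearson). The plot of marker genes gives single genes, in which WT 2iLAF did not always lie nearest WT basal. THY1, a surface marker of primed cells, stood at 716 and 754 TPM in the basal libraries, 65.7 in WT 2iLAF, 14.3 in WT 5iLAF and 37.6 in B3GALT5-KO 2iLAF. DNMT3L, a DNA methyltransferase cofactor of naive cells, stood at 0.04 and 0.04 TPM in the basal libraries, 1.57 in WT 2iLAF, 76.4 in WT 5iLAF and 51.4 in B3GALT5-KO 2iLAF. Globin and granulocyte transcripts did not follow that division, as given with each comparison.

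**Figure D1:**
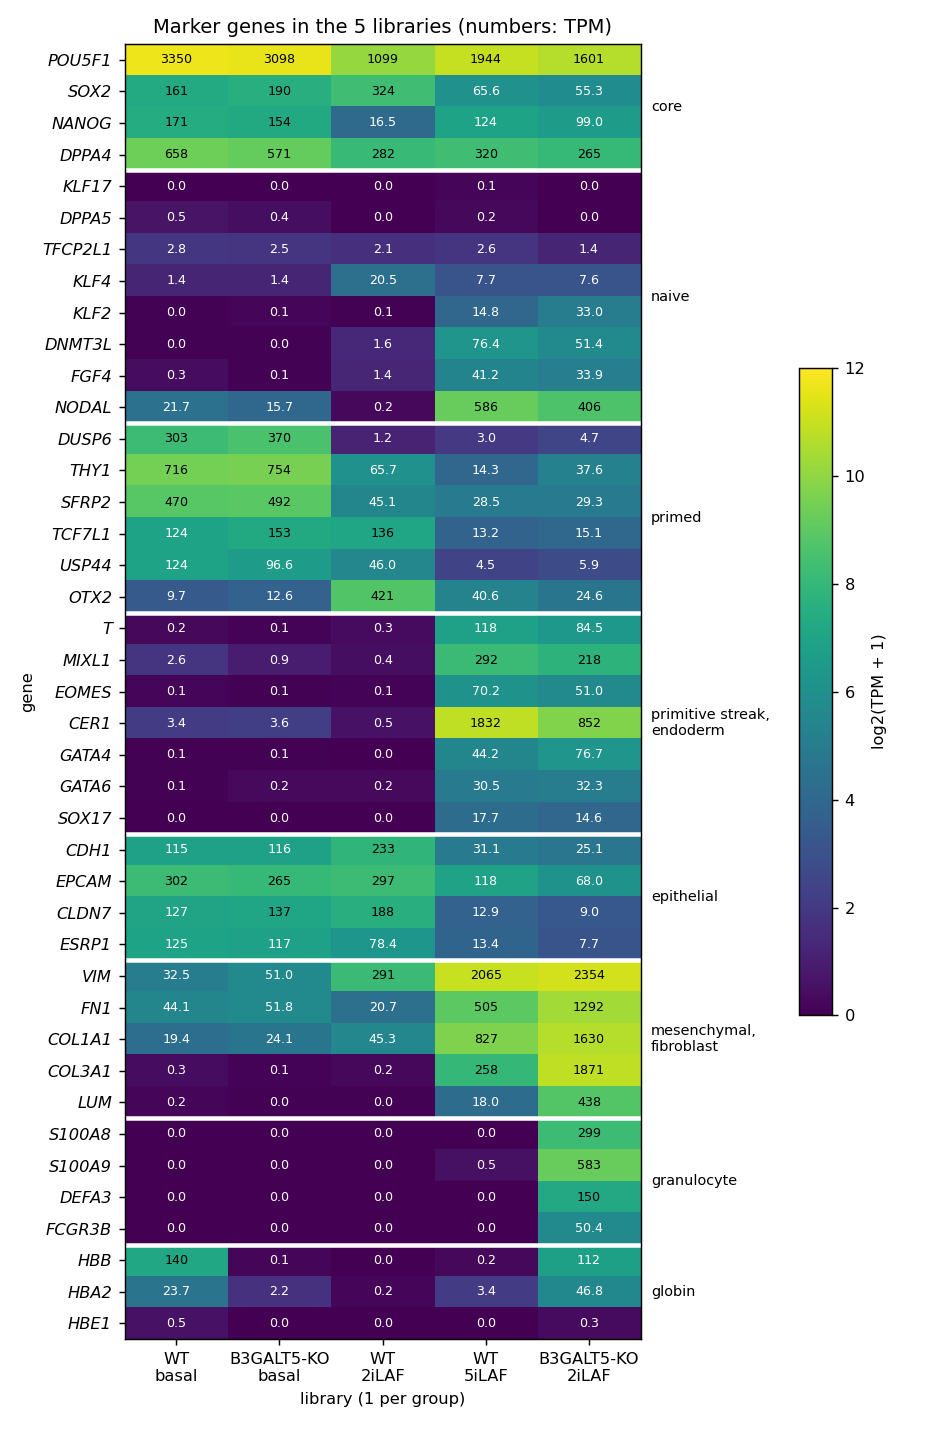
Expression of marker genes (rows) in the 5 libraries (columns), 1 library per group. Colour gives log2(TPM + 1) and the printed numbers give TPM. NODAL reaches 586 TPM in WT 5iLAF and 406 in B3GALT5-KO 2iLAF, against 21.7 in WT basal, while S100A9 reaches 583 TPM in B3GALT5-KO 2iLAF and at most 0.47 in the other libraries.

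Loss of B3GALT5 in basal medium was compared with WT in basal medium. Metallothioneins, the cysteine-rich metal-binding proteins, took the first places among the higher genes. MT2A stood at 574 TPM in B3GALT5-KO against 14.4 in WT, MT1G at 347 against 10.5, MT1E at 229.8 against 4.09, MT1H at 133 against 2.72, and MT1F at 60.1 against 10.7. MT1M stood at 18.2 TPM and was listed at 0 in WT. WT basal held the lowest MT2A of the 5 libraries, since the 2iLAF and 5iLAF libraries stood at 217, 935 and 911 TPM (WT 2iLAF, WT 5iLAF and B3GALT5-KO 2iLAF). CTGF, a secreted target of YAP signalling, stood at 147 against 30.1 TPM, CYP26A1, which degrades retinoic acid, at 11.9 against 2.20, ACTA1 at 21.3 against 4.87, and MIR4435-2HG at 15.2 against 2.99. The lower genes were led by HBB, adult beta-globin, at 0.13 against 140.2 TPM, with HBA1 at 0.32 against 22.9, HBG2 at 0.42 against 23.7 and HBA2 at 2.25 against 23.7. Adult and fetal globin genes together summed to 3.12 against 222 TPM. In WT 2iLAF, WT 5iLAF and B3GALT5-KO 2iLAF they summed to 0.17, 12.1 and 220.6 TPM, so WT basal also stood above the other WT libraries. NLRP2, a maternal-effect gene of the early embryo, stood at 0.21 against 73.1 TPM, and at 84.0 TPM in B3GALT5-KO 2iLAF. ZNF558 was at 0.02 against 15.1, DNAJC15 at 0.11 against 10.7, SIX6 at 0.10 against 17.2, MAGEH1 at 0.36 against 12.4 and ERVMER34-1 at 0.36 against 11.5 TPM. In all, 111 genes were higher and 166 lower by the size rule. With a pseudocount of 0.1 those counts were 327 and 521, and with 5 they were 34 and 40.

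Pluripotency genes were near level between the basal libraries. The core list had a median of -0.11 and no member of 15 passed the size rule, with POU5F1 at 3098 against 3350.3 TPM and SOX2 at 190.0 against 161. L1TD1, an RNA-binding protein of embryonic stem cells, was at 262 against 499 TPM. Naive and primed markers had medians of -0.02 and -0.02, both inside the middle 95% of matched random lists. Among primed markers, STC1 was at 28.1 against 8.25 TPM and HMX2 at 14.1 against 45.0. The 21 p53 targets had a median of -0.60 (interval -0.69 to -0.33), below matched random lists, and 3 passed the size rule as lower. CDKN1A, the p21 cell cycle inhibitor, stood at 0.41 against 5.38 TPM, PHLDA3 at 1.86 against 12.8 and BAX, which promotes apoptosis, at 126 against 278. The p53 median was -0.31 with a pseudocount of 5. Proliferation genes had a median of -0.16, below matched random lists, with MKI67 at 37.3 against 54.9 TPM, and no member of 24 passed the size rule. Neuroectoderm genes OTX1 (11.8 against 2.51 TPM) and SOX3 (28.4 against 10.3 TPM) were higher, in a list whose median was -0.10.

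WT cells in 5iLAF were compared with WT basal. Primed markers were lower, with a list median of -1.74 (interval -2.90 to -0.35) and 16 of 29 members lower against 6 higher. DUSP6, a phosphatase induced by ERK signalling, stood at 2.98 against 303 TPM, THY1 at 14.3 against 716, and USP44 at 4.53 against 124. HMX2 was listed at 0 against 45.0 TPM. Tested naive markers had a median of 1.91 (interval 0.12 to 3.36), above matched random lists, with 12 of 19 higher. Without the filter, which brings the markers near 0 back in, that median was 0.37. With pseudocounts of 0.1 and 5 it was 2.39 and 0.99. FGF4 stood at 41.2 against 0.33 TPM, NODAL at 586 against 21.7, KLF2 at 14.8 against 0.04 and DNMT3L at 76.4 TPM. However, 13 of the 32 naive markers stayed below 1 TPM in all 5 libraries and were not tested. These included KLF17, a transcription factor specific to human naive cells, at 0.12 TPM, DPPA5 at 0.20 and ARGFX at 0.05. TFCP2L1 stood at 2.62 against 2.77 TPM. Core genes were lower in balance (median -0.79), with POU5F1 at 1944 against 3350.3 TPM, NANOG at 124 against 171, and GDF3, a nodal-related ligand, higher at 136 against 13.8. Proliferation genes had a median of -0.68, below matched random lists, and p53 targets 0.44, above them.

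The same WT 5iLAF library carried transcripts of primitive streak, endoderm and mesenchyme. Of 16 mesoderm and primitive streak markers 11 were higher and 1 lower (median 2.23, interval 0.60 to 5.48). That median was 4.44 with a pseudocount of 0.1 and 0.82 with 5. T, brachyury, stood at 118 against 0.21 TPM, MIXL1 at 292 against 2.59, EOMES at 70.2 against 0.12, and HAND1 at 43.5 TPM in WT 5iLAF. Endoderm markers had a median of 2.92, led by CER1, a secreted nodal antagonist, at 1832 against 3.41 TPM, GATA4 at 44.2 against 0.05 and GATA6 at 30.5 against 0.05. WNT target genes had a median of 2.46 with 16 of 20 higher. SP5 reached 109.6 TPM from a listed 0, and CDX1 reached 39.2. Mesenchymal genes were higher in 17 of 18 cases (median 2.55), with VIM, vimentin, at 2065 against 32.5 TPM, while epithelial genes had a median of -1.85. Among epithelial genes ST14 stood at 0.69 against 35.0 TPM and CLDN7 at 12.9 against 127, whereas KRT8, at the highest level in the list, stood at 2163 against 531. Fibroblast and feeder cell markers had a median of 3.25, with COL3A1 at 258 against 0.30 TPM, ACTA2 at 192 against 0.81 and COL1A1 at 827 against 19.4. Trophoblast and amnion markers had medians of 0.59 and 1.45, both above matched random lists, with 7 of 15 and 6 of 9 higher.

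Among the 10 highest ratios of WT 5iLAF against WT basal were also NPPB, natriuretic peptide B, at 840.4 TPM from a listed 0, LEFTY2, a nodal inhibitor, at 1985 against 13.2 TPM, ACTG2 at 494 against 1.46, MYL4 at 287 against 0.49, IGFBP7 at 253 against 0.84, and MEG3, a maternally expressed imprinted RNA, at 138 against 0.01. The lowest included HBB (0.21 against 140.2 TPM), LCK (0.93 against 103), MAL2 (1.28 against 107), CHGA (1.43 against 107), VSNL1 (2.73 against 117) and TMEM59L (0.15 against 44.9). D21S2088E was listed at 0 against 80.4 TPM. The size rule took 1694 genes as higher and 1793 as lower. They were 922 and 796 with a pseudocount of 5.

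WT cells in 2iLAF, the control of the design, were compared with WT basal. Targets of MEK-ERK and FGF signalling were lower, with a median of -1.96 (interval -3.03 to -0.87) and 14 of 19 members lower. DUSP6 stood at 1.24 against 303 TPM, SPRY4 at 1.91 against 97.0, ETV5 at 0.61 against 42.6 and ETV4 at 6.30 against 190.4. NANOG was at 16.5 against 171 TPM, NODAL at 0.18 against 21.7, and LEFTY1, a feedback inhibitor of nodal, at 0.57 against 67.8. Of 8 tested neuroectoderm markers 4 were higher and 0 lower, with a median of 0.90 (interval -0.52 to 6.50), above matched random lists. LHX5, a transcription factor of the forebrain, reached 89.7 TPM and LHX5-AS1 152, both listed at 0 in WT basal, OTX2 stood at 421 against 9.67, SIX3 at 20.1 against 0.08, FEZF1 at 96.6 against 1.63 and SOX21 at 101 against 0.78. CYP26A1 stood at 325 against 2.20 TPM. The highest ratios also held LMO1 (58.9 against 0.14 TPM), GREB1L (41.8 against 0.07), EDN1 (46.9 against 0.34) and PCDH8 (36.5 against 0.16), and the lowest AK4 (1.25 against 111), METTL7A (0.32 against 36.3) and NTS (1.09 against 56.1). HBB and D21S2088E, at 140.2 and 80.4 TPM in WT basal, were listed at 0.

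Naive and primed markers in WT 2iLAF had medians of -0.03 and -0.06, both inside the middle 95% of matched random lists, over members that differed in both directions. Of 19 tested naive markers 3 were higher and 3 lower, and of 29 primed markers 4 were higher and 9 lower. Core genes had a median of -1.11 (interval -2.06 to 0.96), below matched random lists, with 8 of 15 lower and 3 higher, and POU5F1 at 1099 against 3350.3 TPM. KLF4 stood at 20.5 against 1.40 TPM, while THY1 was at 65.7 against 716 and SFRP2 at 45.1 against 469.7. Primitive streak and endoderm markers had medians of 0.02 and 0.02, and WNT targets 0.00, also inside that range. Trophoblast markers had a median of 0.73, above it, with TFAP2A at 17.3 against 0.06 TPM, TFAP2C at 36.5 against 3.72 and GATA3 at 6.70 against 0.34. Epithelial genes had a median of 0.32, above matched random lists, with CLDN4 at 111 against 29.7 TPM and CDH1, E-cadherin, at 233 against 115. Proliferation genes had a median of -0.42, below them, with TOP2A at 99.4 against 269 TPM, and p53 targets 0.50, above them. Amnion markers had a median of 0.00, inside the range. By the size rule 745 genes were higher and 1107 lower, so 40.2% of the counted genes were higher. A pseudocount of 0.1 gave 1208 and 1789, and 5 gave 351 and 454. The median over all genes was -0.13, and after median-ratio scaling, which brought it to 0.00, 997 genes were higher and 844 lower, or 54.2% higher.

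B3GALT5-KO cells in 2iLAF were compared with B3GALT5-KO basal. Primed markers had a median of -2.05 (interval -3.23 to -0.88) with 19 of 29 lower, among them DUSP6 at 4.66 against 369.9 TPM and SLC7A3, a cationic amino acid transporter, at 7.31 against 260.2. Tested naive markers had a median of 1.86 (interval 0.65 to 4.05) with 14 of 19 higher, among them FGF4 at 33.9 against 0.06 TPM, KLF2 at 33.0 against 0.14 and NODAL at 406 against 15.7. KLF17, DPPA5 and ARGFX were listed at 0 in B3GALT5-KO 2iLAF. Without the filter, which brings the markers near 0 back in, the naive median was 0.34. With pseudocounts of 0.1 and 5 it was 2.39 and 0.98. Primitive streak markers had a median of 2.99 (5.01 with a pseudocount of 0.1 and 1.30 with 5), with HAND1 at 135 TPM, MIXL1 at 218 against 0.90 and T at 84.5 against 0.09. Endoderm markers had a median of 2.40, with CER1 at 852 against 3.63 TPM. Mesenchymal genes were higher in 17 of 18 cases, with VIM at 2354 against 51.0 TPM and SNAI2 at 47.3 against 0.60. Epithelial genes had a median of -1.95, with RAB25 at 3.03 against 89.3 TPM. The p53 targets had a median of 1.03, above matched random lists, with CDKN1A at 48.8 against 0.41 TPM. That list was also above them in both WT medium comparisons, and its median difference between the medium changes of knockout and WT in 2iLAF, 0.57, lay inside the middle 95%. Proliferation genes had a median of -0.58, below matched random lists, amnion markers 1.26, above them, and trophoblast markers 0.37, inside their middle 95%.

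The highest ratios of B3GALT5-KO 2iLAF against B3GALT5-KO basal were those of COL3A1, a fibrillar collagen, at 1871 against 0.08 TPM, and H19, an imprinted RNA, at 2762 against 2.81. IGF2, which shares its imprinted locus with H19, stood at 711 against 1.91 TPM, ACTA2 at 555 against 0.20, LUM, lumican, at 438 against 0.04, MEG3 at 274 against 0.01 and NPPB at 311 against 0.35. MYL4 was at 645 TPM from a listed 0. S100A9 and S100A8, calcium-binding proteins of neutrophils, stood at 583 and 299 TPM and were listed at 0 in B3GALT5-KO basal. Granulocyte genes summed to 1668 TPM in the 2iLAF library against 11.7 in basal, beside the gene groups above. The lowest ratios were those of DUSP6, FOXD3-AS1 (4.34 against 288 TPM), WFDC2 (1.05 against 104), CHGA (1.32 against 104), VSNL1 (3.18 against 185), IGSF21 (0.11 against 45.0), TMEM59L (0.60 against 60.5) and LCK (1.37 against 73.2). The counts were 2502 higher and 1866 lower, and 2454 and 1862 without the blood cell genes. They were 1351 and 878 with a pseudocount of 5.

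**Figure D2:**
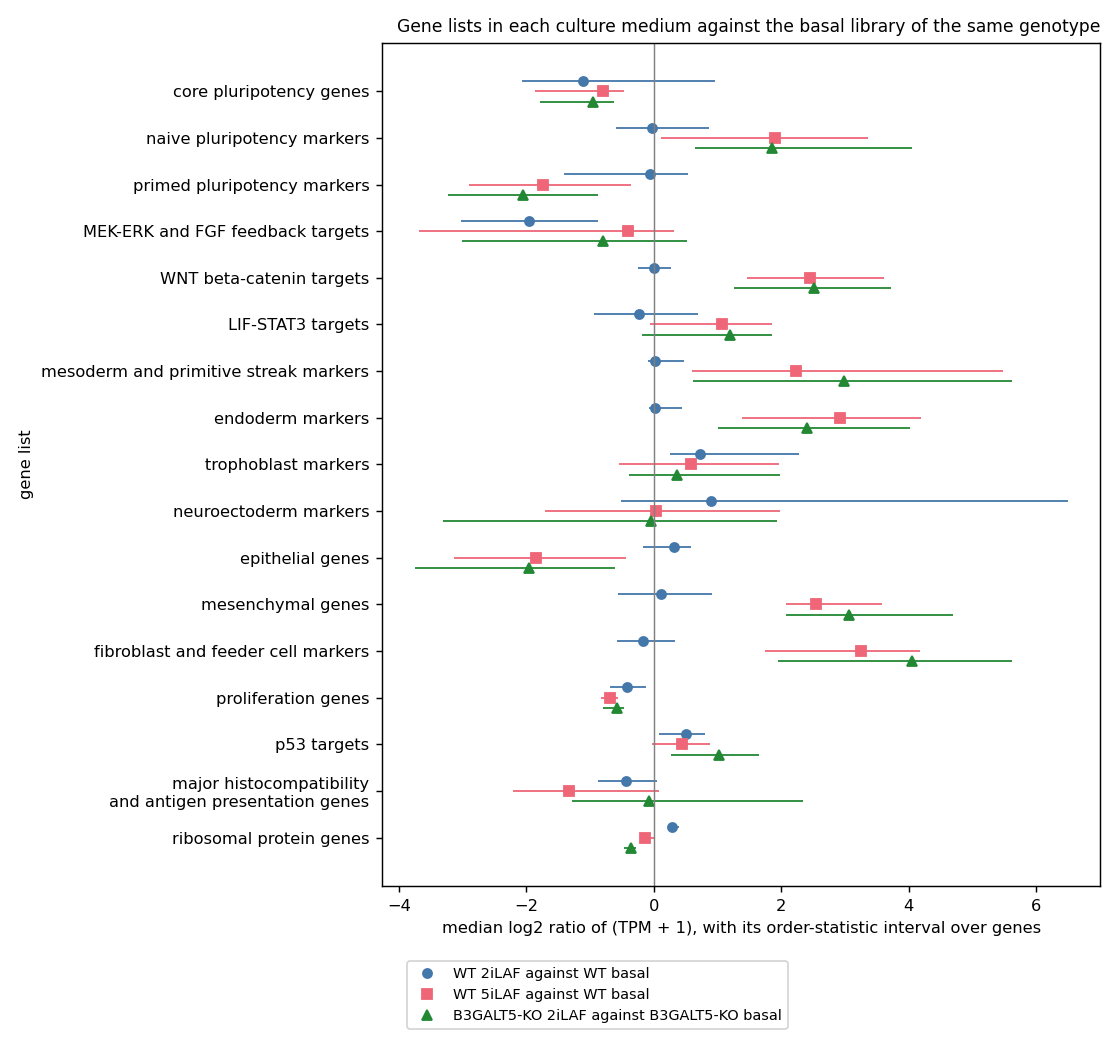
Median log2 ratio of (TPM + 1) of gene lists (rows) in WT 2iLAF, WT 5iLAF and B3GALT5-KO 2iLAF, each against the basal library of the same genotype. Points are medians over tested members, lines their order-statistic 95% intervals over genes, and each group is 1 library. Primed markers lie at -0.06, -1.74 and -2.05 in that order, and WNT targets at 0.00, 2.46 and 2.52.

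The knockout and WT cells were then compared within 2iLAF. NODAL stood at 406 TPM in B3GALT5-KO and 0.18 in WT, LEFTY2 at 1385 and 0.32, and CER1 at 852 and 0.48. COL3A1 was at 1871 against 0.19 TPM, LUM at 438 against 0.04, AQP1, a water channel, at 352 against 0.08 and H19 at 2762 against 10.9. S100A9 and S100A8 again stood at 583 and 299 TPM and were listed at 0 in WT 2iLAF, and granulocyte genes summed to 1668 against 5.87 TPM. The 8 tested neuroectoderm markers had a median of -0.64 (interval -6.50 to 1.17), inside the middle 95% of matched random lists, with 4 lower and 1 higher. Single neural genes of WT 2iLAF were lower in the knockout, with FEZF1, LHX5 and LHX5-AS1 listed at 0 against 96.6, 89.7 and 152 TPM and SOX21 at 2.01 against 101. PPP1R1B stood at 0.08 against 110.4 TPM, WFDC2 at 1.05 against 156, TTYH1 at 0.23 against 86.2, PMEL at 3.50 against 213, CLDN4 at 2.01 against 111 and FAM57B at 0.11 against 34.9. Tested naive markers, 19 of 32, had a median of 2.17 (interval -0.11 to 3.85), above matched random lists. That median leaves out the 13 naive markers below 1 TPM in all libraries. Primed markers had a median of -1.21 (interval -2.28 to -0.08), below matched random lists. Medians were 4.11 for fibroblast markers with 21 of 23 higher, 2.99 for mesenchymal genes with 15 of 18, 2.72 for primitive streak markers with 13 of 16, and 2.5 for endoderm markers with 11 of 16. MEK-ERK targets had a median of 1.34, with IER3 at 101 against 7.97 TPM and MYC at 54.3 against 11.8, although DUSP6 was low in both, at 4.66 and 1.24. Against basal medium that list was below matched random lists in both genotypes, with medians of -0.79 in B3GALT5-KO 2iLAF and -1.96 in WT 2iLAF. In WT 5iLAF its median was -0.40, inside the middle 95%. NANOG stood at 99.0 against 16.5 TPM and SOX2 at 55.3 against 324. The size rule took 2620 genes as higher and 1705 as lower, and 2571 and 1703 without the blood cell genes. They were 1416 and 779 with a pseudocount of 5. The median over all genes was 0.10, and after median-ratio scaling 2471 genes were higher and 1936 lower.

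The change from basal medium to 2iLAF was set side by side for the 2 genotypes by subtracting the log2 ratio in WT from that in B3GALT5-KO. For NODAL that difference was 8.87 and for COL3A1 10.89, while for OTX2 it was -4.39 and for LHX5 -6.56. The list median of the difference was 2.24 (interval 0.16 to 4.35) for the 19 tested of 32 naive markers. It was -1.14 for primed markers, 2.20 for WNT targets, 2.57 for primitive streak markers and 3.05 for mesenchymal genes. At a size of 1 or more, 3016 genes had a medium change higher in the knockout and 1729 a lower one, which became 1617 and 813 with a pseudocount of 5. The median difference over all genes was 0.19, so part of that excess goes with library scale. After median-ratio scaling the counts were 2628 and 2106. With 1 library in each combination the interaction of genotype and medium could not be tested.

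B3GALT5-KO 2iLAF and WT 5iLAF, the libraries recorded as naive, were compared directly. Pluripotency lists were close, with medians of -0.06 for naive markers (inside the middle 95% of matched random lists), -0.11 for primed markers and -0.27 for core genes (both below it). No core gene of 15 passed the size rule. POU5F1 stood at 1601 and 1944 TPM and NANOG at 99.0 and 124. Genes of the granulocyte and globin lists led the highest ratios. S100A9 stood at 583 against 0.47 TPM. S100A8 at 299 TPM, the neutrophil defensins DEFA3, DEFA1B and DEFA1 at 150.1, 148 and 141, FCGR3B, a neutrophil Fc receptor, at 50.4 and S100A12 at 41.1 were each listed at 0 in WT 5iLAF. Granulocyte genes summed to 1668 against 26.3 TPM and adult and fetal globin genes to 220.6 against 12.1. HBB stood at 112 against 0.21 TPM and SRGN, serglycin of secretory granules, at 58.5 against 0.70. DCN, decorin, was also among the 10, at 48.3 against 0.33 TPM. Fibroblast and feeder cell markers had a median of 0.86 (interval 0.52 to 1.33), with LUM at 438 against 18.0 TPM, COL6A3 at 99.6 against 8.58 and COL3A1 at 1871 against 258. Beside these granulocyte values, antigen presentation genes had a median of 1.32, with HLA-B at 138 against 13.8 TPM and B2M at 530.1 against 145. IGF2 was at 711 against 54.9 TPM and H19 at 2762 against 253.

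Lower in B3GALT5-KO 2iLAF than in WT 5iLAF were the natriuretic peptides NPPA (2.52 against 19.9 TPM) and NPPB (311 against 840.4), HLA-DQB1 (18.5 against 62.9), FGF17 (43.0 against 122), GSTT1 (9.34 against 28.1), TMC5 (4.46 against 14.3) and TAGLN3 (4.87 against 14.9). The RNAs LOC729739, LINC00545 and LINC01002 stood at 9.70, 6.32 and 13.4 TPM against 30.5, 20.4 and 38.4. Endoderm markers had a median of -0.28, below matched random lists, with CER1 at 852 against 1832 TPM. By the size rule 772 genes were higher and 163 lower, and without the blood cell genes 731 and 163. With a pseudocount of 0.1 the counts were 1211 and 500, and with 5 they were 292 and 31.

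Medium changes were compared between genotypes over pairs of libraries that share none. The ratios of WT 5iLAF against WT basal and of B3GALT5-KO 2iLAF against B3GALT5-KO basal had a Pearson correlation of 0.840 across genes (Spearman 0.821), and NODAL, CER1, VIM and DUSP6 lay on the same side in both. Of 1694 and 2502 higher genes 1395 were shared, where independent lists would share 268.9, and of 1793 and 1866 lower genes 1295 were shared, where independent lists would share 212.3. The ratios of WT 2iLAF against WT basal had a correlation of 0.268 with those of B3GALT5-KO 2iLAF (Spearman 0.258). There 309 of 745 genes higher in WT 2iLAF were also higher in the knockout, beside 118.3 for independent lists, and 415 of 1107 were lower in both, beside 131.1. The shared genes numbered 597 and 669 with a pseudocount of 0.1 and 138 and 170 with 5, and those shared with WT 5iLAF 773 and 596 with 5. Genes lower in both included DUSP6, SPRY4 and ETV5.

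**Figure D3:**
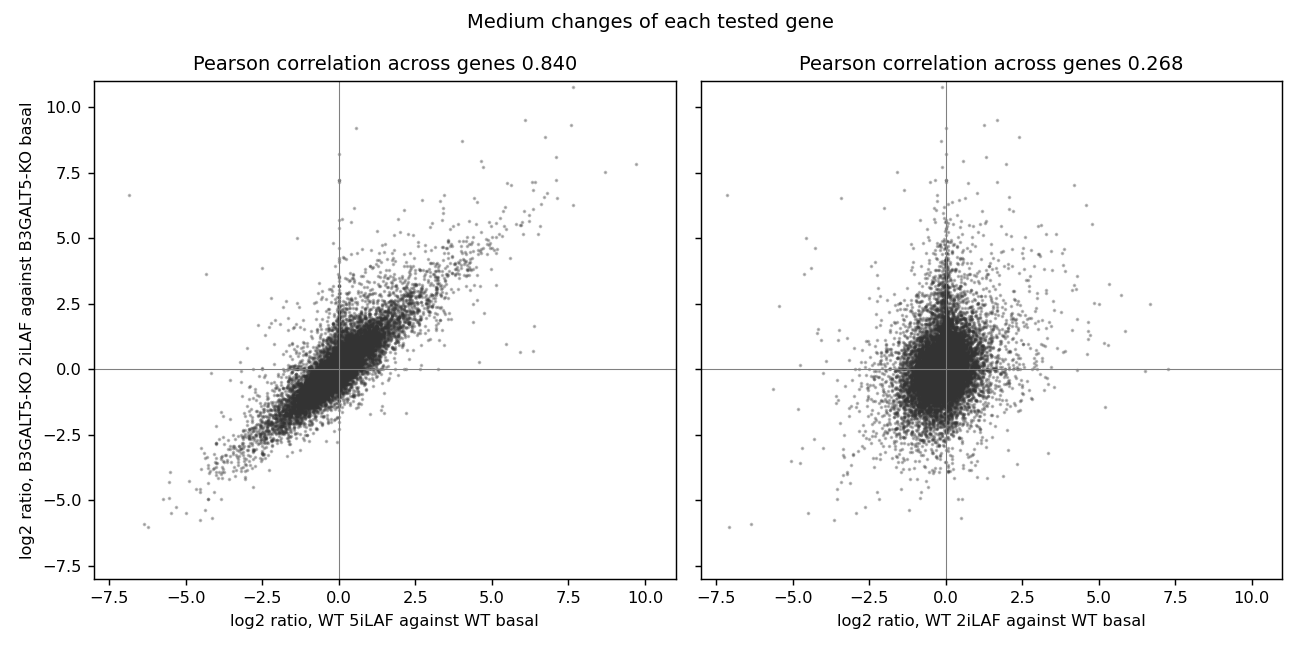
Log2 ratio of each of 15761 tested genes in B3GALT5-KO 2iLAF against B3GALT5-KO basal (vertical axis) and in WT 5iLAF (left) or WT 2iLAF (right) against WT basal (horizontal axis). Each point is a gene, and no library is shared between the axes. The correlations across genes are 0.840 on the left and 0.268 on the right.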

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

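Both results below were picked out because their list medians lay on opposite sides of 0 for the same change of medium in WT and in B3GALT5-KO cells, with both medians outside the middle 95% of matched random lists. The difference was not tested, because each combination of genotype and medium holds 1 library. For the 17 epithelial genes, the median log2 ratio of 2iLAF against basal medium was 0.32 in WT and -1.95 in B3GALT5-KO, and the median of the gene-wise differences was -2.29. CLDN4 stood at 29.7 and 111 TPM in WT basal and WT 2iLAF, and at 49.2 and 2.01 TPM in the knockout libraries of those media. For the 18 heat shock and unfolded protein response genes the medians were -0.72 in WT and 0.53 in B3GALT5-KO, and the median difference was 1.2. In the same order of libraries, HSPA1A stood at 79.5 and 21.2 TPM in WT and at 37.8 and 55.1 TPM in the knockout, and ATF3 at 14.4 and 14.5 and at 19.2 and 107. Other cell type markers moved with both lists, as the median difference was 4.11 for fibroblast and 3.05 for mesenchymal genes, and granulocyte genes summed to 1668 TPM in B3GALT5-KO 2iLAF against 5.87 in WT 2iLAF. In WT 5iLAF against WT basal, with no knockout, the medians were -1.85 for epithelial genes and 0.10 for heat shock genes, the latter inside the middle 95% of matched random lists.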

How the results depend on the processing

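Each group holds 1 library, so no library could be left out, no spread between cultures was available, and depth is unknown. Counts and medians can therefore be set only against other settings. FPKM in place of TPM, leaving out the blood cell genes and taking blood cell lists whole were chosen after seeing the data, and all other settings were planned. No paired analysis was possible because there are no replicates to pair. Over all alternatives, 109 gene counts stayed within 1.5 times the main count and 59 did not. Of list medians 1808 stayed within the interval of the main median, 39 moved further and 1 changed sign. Many of these intervals are wide. The naive median in WT 5iLAF against WT basal counts as staying at 0.37 in place of 1.91, within 0.12 to 3.36. The tallies are therefore no measure of stability. Of correlations 1 stayed and 11 moved. The range counted as staying was narrow for correlations. For WT 5iLAF and B3GALT5-KO 2iLAF, 0.972 with FPKM in place of 0.970 counted as moved. That tally is therefore no measure of instability either. Across the alternatives this correlation lay between 0.946 and 0.985, and that of WT 2iLAF and B3GALT5-KO 2iLAF between 0.790 and 0.930. Low genes weigh less with a larger pseudocount and a larger size rule counts fewer genes by construction. FPKM values stood between 0.484 and 0.531 of TPM, so the same pseudocount and filter weigh more in FPKM, also by construction. For the other settings the cause was not tested.

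Counts are given as higher and then lower. With a pseudocount of 0.1, B3GALT5-KO basal against WT basal gave 327 and 521 genes in place of 111 and 166. WT 2iLAF against WT basal gave 1208 and 1789 in place of 745 and 1107, and B3GALT5-KO 2iLAF against WT 5iLAF gave 1211 and 500 in place of 772 and 163. The overlap of the 2iLAF changes in both genotypes was 597 and 669 in place of 309 and 415. The Pearson correlation of B3GALT5-KO 2iLAF was 0.946 with WT 5iLAF and 0.794 with WT 2iLAF, in place of 0.970 and 0.856. The primitive streak medians were 4.44 in WT 5iLAF and 5.01 in B3GALT5-KO 2iLAF, in place of 2.23 and 2.99, within their intervals.

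With a pseudocount of 5, B3GALT5-KO basal against WT basal gave 34 and 40 genes, WT 5iLAF against WT basal 922 and 796, and WT 2iLAF against WT basal 351 and 454. B3GALT5-KO 2iLAF gave 1351 and 878 against B3GALT5-KO basal, 1416 and 779 against WT 2iLAF, and 292 and 31 against WT 5iLAF. The difference of medium changes gave 1617 and 813. The knockout 2iLAF changes shared 773 and 596 genes with WT 5iLAF and 138 and 170 with WT 2iLAF. The correlations were 0.980 and 0.887 in the order above, and the p53 median between basal libraries was -0.31 in place of -0.60. The primitive streak medians were 0.82 in WT 5iLAF and 1.30 in B3GALT5-KO 2iLAF, and the naive medians 0.99 and 0.98 in place of 1.91 and 1.86.

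Without a filter the correlations were 0.985 and 0.930, and the naive marker median in B3GALT5-KO 2iLAF against B3GALT5-KO basal was 0.34 in place of 1.86 and that in WT 5iLAF against WT basal 0.37 in place of 1.91, because markers near 0 in all libraries enter. With genes reaching 5 TPM, B3GALT5-KO basal against WT basal gave 73 and 109 genes, B3GALT5-KO 2iLAF against WT 5iLAF gave 464 and 107, and the correlations were 0.961 and 0.790. The germ cell median in WT 5iLAF against WT basal was -0.81 and turned to 2.76 there, because fewer of its 9 genes enter. With FPKM, B3GALT5-KO basal against WT basal gave 70 and 90 genes, WT 2iLAF against WT basal had 679 lower, and B3GALT5-KO 2iLAF against WT 5iLAF gave 497 and 91. The FPKM correlations were 0.972 and 0.850. Without the blood cell genes the correlation of WT 5iLAF and B3GALT5-KO 2iLAF was 0.974.

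With a size rule of 4-fold the counts were 12 and 32 for B3GALT5-KO basal against WT basal, 615 and 476 for WT 5iLAF against WT basal, and 208 and 184 for WT 2iLAF against WT basal. For B3GALT5-KO 2iLAF they were 932 and 496 against B3GALT5-KO basal, 971 and 449 against WT 2iLAF, and 215 and 11 against WT 5iLAF. With 1.5-fold they were, in the same order of comparisons, 447 and 754, 2918 and 3472, 1609 and 3126, 4071 and 3511, 4351 and 3043, and 1431 and 723. Median-ratio and trimmed-mean scaling moved no gene count given here by over 1.5 times. The higher and lower genes of WT 2iLAF against WT basal, 745 and 1107, were 997 and 844 with median-ratio scaling and 951 and 869 with trimmed-mean scaling.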

Other observations

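The lists of imprinted, LIF, germ cell, cholesterol, ribosomal, hypoxia, glycolysis and histone genes were planned and the test of embryonic globin was fixed before its result was seen, while the X-linked set and all other tests of explanations were chosen after the results were seen. Imprinted genes were above matched random lists in each medium comparison within a genotype. Their median was 0.50 in WT 5iLAF, 0.17 in WT 2iLAF and 1.10 in B3GALT5-KO 2iLAF, each against basal medium. DLK1, a paternally expressed gene, stood at 25.4 TPM in WT 2iLAF against 0.36 in WT basal. Targets of LIF and STAT3 had medians of 1.08 in WT 5iLAF, -0.23 in WT 2iLAF, and a median above matched random lists in B3GALT5-KO 2iLAF. JUNB stood at 5.13 TPM in WT basal, 5.34 in WT 2iLAF, 31.9 in WT 5iLAF and 45.5 in B3GALT5-KO 2iLAF. DNMT3B, a de novo DNA methyltransferase, stood at 133 TPM in WT 5iLAF against 754 in WT basal.

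WT 2iLAF differed from WT basal in further groups. Of 18 germ cell genes 9 were tested, with a median of 0.91 (interval -0.64 to 2.99). Of these, 4 were higher, among them SOX15 at 84.3 against 5.28 TPM and DAZL at 9.93 against 0.89. Cholesterol synthesis genes had a median of -0.63, with CYP51A1 at 42.4 against 103 TPM, and ribosomal protein genes a median of 0.29, with RPLP0 at 6783 against 4449. Between the basal libraries, hypoxia genes had a median of 0.27, glycolysis genes 0.12 and replication-dependent histone genes -0.41, outside the middle 95% of matched random lists. MXI1, a hypoxia-induced gene, stood at 15.1 TPM in B3GALT5-KO basal against 6.97 in WT basal. The 372 X-linked genes with a mean of at least 5 TPM had medians of -0.17 between the basal libraries, 0.12 in WT 5iLAF, -0.13 in WT 2iLAF and 0.48 in B3GALT5-KO 2iLAF, each against basal medium. In B3GALT5-KO 2iLAF they were 0.43 against WT 2iLAF and 0.20 against WT 5iLAF. The median in WT 2iLAF against WT basal lay inside the middle 95% of matched random lists and equalled the median of -0.13 over all genes, the one between the basal libraries lay below that range, and the others lay above it.

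Granulocyte genes summed to 1668 TPM in the B3GALT5-KO 2iLAF library, with 25 of 25 at or above 1 TPM, and to at most 26.3 TPM in the other libraries, where at most 2 reached 1 TPM. The blood cell lists were written after these data had been seen. Their high values and percentiles in this library describe it and are no independent support for a source. For the globin transcripts, blood formation within the culture was argued against by embryonic globin, as HBE1 and HBZ summed to 0.68 TPM and stood at 0.0060 of HBB. The 10 genes for other proteins of the red cell did not follow the globin sums. They summed to 38.7 TPM in WT basal and 36.7 in B3GALT5-KO basal, and to 27.8 in WT 5iLAF and 29.25 in B3GALT5-KO 2iLAF. Blood cell lists were also taken whole, without the filter, against WT 5iLAF and random lists matched on its level. The 20 T and NK cell genes had a median of 0.83 at percentile 100 and the 15 B cell genes 0.15 at 98.48. However, B cell genes summed to 8.19 TPM there, below 12.9 in WT basal and 10.5 in B3GALT5-KO basal. The 10 red cell protein genes had a median of 0.33 at 99.83. The 12 platelet genes had a median of 0.05 at 88.77, inside the middle 95%. Human blood or bone marrow RNA mixed into the B3GALT5-KO 2iLAF library therefore stays open. The 14 blood progenitor genes, taken in the same way, had a median of 0.38 at percentile 99.94, but 96.15 for the 7 passing the filter, and summed to 52.8 TPM against 31.1, so blood formation stays open for the leukocyte transcripts. For these the sources cannot be told apart, and adult and fetal globin genes also summed to 222 TPM in WT basal, where granulocyte genes summed to 18.3, so RNA from another source stays open for that library too and was not tested there.

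Primitive streak, endoderm and fibroblast genes were higher together in WT 5iLAF and B3GALT5-KO 2iLAF. RNA of fibroblast feeder cells, as a source shared with the fibroblast genes, was examined through the ratio of B3GALT5-KO 2iLAF to WT 5iLAF. The endoderm median was -0.28 (interval -0.71 to 0.10) and the fibroblast median 0.86 (interval 0.52 to 1.33), so the endoderm genes did not rise with the fibroblast genes. That does not decide on a shared source, which was taken to keep 1 ratio. The fibroblast genes themselves did not keep 1 ratio, with COL6A2 at 0.53 and COL6A3 at 3.39. For the primitive streak genes the median of -0.12 had an interval of -0.47 to 1.35, which overlaps that of the fibroblast genes and leaves such a source open, as it is for the fibroblast genes themselves. A primitive streak median of 2.3 in WT 5iLAF against WT basal after median-ratio scaling argues against library scaling. Differentiation of part of each culture may account for these genes, and that was not tested.

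In B3GALT5-KO basal, 10 genes that stood at 3 TPM or more in each WT library were below 0.5 TPM, NLRP2, DNAJC15, ZNF558 and CDKN1A among them, and p53 targets were lower. Such genes were not particular to that library. With the same cutoffs set against all other libraries, 9 genes were low in B3GALT5-KO basal alone and 14 in WT 2iLAF alone. The counts were 1 in WT basal, 2 in WT 5iLAF and 0 in B3GALT5-KO 2iLAF. A lasting silencing common to both knockout libraries was argued against, since 0% of the 10 stayed below 0.5 TPM in B3GALT5-KO 2iLAF and 9 reached 3 TPM. Silencing in the basal culture alone stays open, because both libraries are not known to come from the same clone. For the same reason, the p53 median of 0.13 in B3GALT5-KO 2iLAF against WT 2iLAF does not decide on a lasting loss of p53 function. In that comparison fibroblast markers had a median of 4.11 and granulocyte genes summed to 1668 against 5.87 TPM. Transcripts of p53 targets from other cells could therefore not be set apart. Library scaling was argued against by a p53 median of -0.52 between the basal libraries after median-ratio scaling. The knockout libraries may come from different clones or passages, or the state may be reversed by the medium. Neither of these was tested, and the labels give 1 library for each.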
